A study of Mus musculus with 24 samples.

How the data were processed

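Total RNA from gonadal adipose tissue, liver, kidney and aorta of Glo1+/- and wild-type (WT) mice was measured on 24 Illumina expression bead arrays, 3 for each genotype in each of 4 tissues. Per the labels, the mice were 36 weeks old, of strain C57BL/6J and female, and the Glo1+/- animals were heterozygous knockouts from a re-derived line kept on standard chow. Tissue was flash frozen, RNA was isolated with RNeasy mini columns, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. Each array carries RNA of 1 tissue sample. The labels do not say whether samples of different tissues with the same replicate number came from the same animal.

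The deposited values are on a log2 scale, or on a log2-like variance-stabilised scale that the values do not tell apart from it, so the fold changes of dim probes can be understated. They run from 7.96 to 15.38 with a floor near 8, and no value is missing. Per the submitters' processing notes, the values were made with lumi 2.32.0. The background correction, the transformation and the normalization method are not given in the sources used here. Array medians lie between 8.23 and 8.25, close to the floor. The upper quartiles lie between 9.19 and 9.30, the 95% points between 11.79 and 11.89 and the maxima between 14.96 and 15.38, so the 24 arrays have similar and not identical distributions. Detection p-values were not used here, and no probe was removed before testing. The number of arrays, 3 per group, limits the precision.

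The table holds 25697 probes. The platform annotation gives 1 gene for 23978 of them, several genes for 0 and none for 1719, and these probes name 16593 distinct genes. Gene IDs of 23962 probes were found in the reference gene table of assembly GRCm38.p6, which changed 0 symbols. That assembly served for gene names and for which genes neighbour each other, and no position is given because the sources name no build. No probe's level was set against another probe's level as a difference in abundance between genes.

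Each tissue was tested on its own 6 arrays with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend on the mean value, 2-sided, and Benjamini-Hochberg adjustment over all probes. A probe is called at an adjusted p under 0.05. All adjusted p-values of probes below are limma's. An exact test of 3 against 3 arrays cannot give a p under 0.1, so single probes have no exact test. A fit of all 24 arrays with 8 group means gave the average genotype effect over the 4 tissues and, with an F test of the interaction, the difference of the genotype effect between tissues. Errors after ± are standard errors from limma for differences and SD for group means. Correlations of genotype effects between tissues were taken across 16593 genes, which are not independent replicates, and set beside 100 regroupings of the arrays within each tissue.

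The 42 gene lists, 18 of them markers of cell types, hold 1470 symbols, of which 1310 matched the annotation. They cover dicarbonyl detoxification, receptors of advanced glycation end products (AGE), NRF2 and glutathione, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation with PPAR alpha targets, and adipocyte genes. They also cover brown and beige adipocytes, oxidative phosphorylation, glycolysis, gluconeogenesis and insulin signalling, bile acid and lipoprotein metabolism, drug-metabolising P450 and conjugation enzymes, the unfolded protein response, heat shock, immediate early genes, and the circadian clock. Inflammation is covered by the interferon response, by inflammatory cytokines and chemokines and by the acute phase, and tissue remodelling by extracellular matrix and fibrosis and by the cell cycle. Sex-biased liver genes, genes of kidney injury, the Glo1 segment and proximal chromosome 17 around Glo1 complete these. Cell types are macrophage, lymphocyte, neutrophil, erythroid cell, mast cell, endothelium, contractile smooth muscle, skeletal and heart muscle, Schwann cell and neuron, ovary with uterus and oviduct, mammary and other epithelium, mesothelium, exocrine pancreas, hepatocyte, kidney tubule, and glomerulus with podocyte. In each tissue a gene was taken by its probe with the highest mean and counted as measured when that mean lay above the median of all probes of the tissue. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and adjusted over the lists of the tissue. Beside it stand camera with a correlation estimated per list and fry, which asks whether the genes of a list move 1 way on balance. Counts of changed members are given over all probes and adjusted over the list alone.

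These choices were made before the data were examined: the tests, the gene lists, the alternatives and the rule for named genes. Glo1 and Nnt are named in every tissue. Named per tissue are up to 12 rising and 12 falling genes with the largest changes among called probes above the median whose 3 Glo1+/- values all lie on the same side of the 3 WT values. Where fewer than 12 passed in a direction, the list was filled to 8 with the genes of smallest unadjusted p, which did not pass. For each called list up to 4 measured members with its shift and 1 against it are named. For the average effect and for the difference between tissues the 12 probes of smallest adjusted p are named, and of the proximal chromosome 17 list every member with an unadjusted p under 0.05. A few genes of known relevance to a tissue are named always. Genes named outside this rule, and the lists for epididymis and male tract, thymocytes and sex chromosomes, were chosen after their values were seen.

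Pairing by replicate number was checked before any paired fit, by the correlation of deviations from the group means across the 12848 brighter probes of a tissue. In adipose tissue the same-numbered libraries correlated at 0.667, 0.170 and 0.336, all above the limit of 0.1 used here. Number 2 correlated better with another number (0.293), so the data pair these libraries only in part, and the labels do not pair them. A fit with the replicate number as a block therefore stands beside the adipose results where it changes them. The arrays lie on 3 slides. All adipose arrays share slide 1 and all aorta arrays share slide 3, so slide cannot act within these tissues. Position on the slide goes with genotype there: WT holds A to C and Glo1+/- D to F in adipose tissue, and C to E and F to H in aorta. An effect of position cannot be told apart from genotype. In liver and kidney the WT arrays also come before the Glo1+/- arrays in order. Slide 2 holds WT liver 3 with Glo1+/- liver 1 to 3, and WT kidney 1 to 3 with Glo1+/- kidney 1. In liver and kidney a fit with slide as a block equals the comparison within slide 2, because the other slide holds only 1 genotype of the tissue.

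The procedure was tested on simulated data with the mean, spread and array numbers of each comparison. Of probes changed by 0.5, 1 and 2 log2 units, the test recovered 52.2%, 85.1% and 98.5% in adipose tissue, and 79.1%, 100% and 100% in liver. In kidney it recovered 95.5%, 100% and 100%, and in aorta 19.4%, 43.3% and 93.9%. False calls made up 2.48%, 2.11%, 6.64% and 5.45% of the calls in that order. For the average effect it recovered 94.0%, 100% and 100% with 8.84% false calls. For the difference between tissues, simulated with changes in liver only, it recovered 34.3%, 83.6% and 97.0%. There 71 false calls made up 33.2% of the calls, which a spread fitted per tissue lowered only to 31.9%. Changes limited to another tissue were not simulated. A list shifted by -0.3 was called in all 4 tissues with the preset correlation and 0 other lists were. Genes were drawn independently of each other, so false list calls from genes that move together were not simulated. With an estimated correlation the shifted list was called in adipose tissue, kidney and aorta, and missed in liver at an adjusted p of 0.0941.

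Alternatives changed 1 choice at a time, except slide as a block in the fit of all 24 arrays, which differs from the fit of a tissue in 2 choices: all 24 arrays in a single fit, brighter probes only, quantile or cyclic loess normalization repeated within a tissue, centring on array medians, eBayes without a trend or with robust settings, array weights, the mean of a gene's probes, replicate number or slide as a block, and leaving out each library or tissue in turn. Alternatives chosen after seeing the data left out the library labelled Glo1+/- aorta 3, both aorta libraries labelled 3, or both adipose libraries numbered 1. Others kept only probes not brighter in liver or kidney than in adipose tissue, or fitted a spread per tissue. Random blocks were fitted with statmod 1.5.0.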

Results

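Expression was compared between mice heterozygous for a Glo1 knockout (Glo1+/-) and WT mice in gonadal adipose tissue, liver, kidney and aorta, with 3 libraries per genotype and tissue. Glo1 encodes glyoxalase 1, which detoxifies the reactive dicarbonyl methylglyoxal. The comparison asks which transcripts differ with loss of 1 Glo1 allele in each tissue of 36-week-old animals. Array medians lay between 8.23 and 8.25 on the log2 scale. Across probes, which are not independent replicates, libraries of the same tissue correlated at 0.952 to 0.993 in adipose tissue, 0.986 to 0.996 in liver, 0.991 to 0.996 in kidney and 0.924 to 0.994 in aorta.

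Glo1 itself, read by 1 probe, was lower in the Glo1+/- mean of every tissue. In liver it fell by 0.88 ± 0.11 (adjusted p = 0.0031), with values of 13.91, 14.16 and 13.85 in WT and 13.22, 12.90 and 13.14 in Glo1+/-. In kidney it fell by 0.88 ± 0.15 (adjusted p = 0.022), from 12.51, 12.62 and 12.45 to 11.56, 11.31 and 12.06. In adipose tissue the change was -0.90 ± 0.18 (adjusted p = 0.239), with 12.29, 12.30 and 12.004 in WT and 11.55, 10.92 and 11.43 in Glo1+/-, so the groups did not overlap although the probe did not pass. Aorta gave -0.63 ± 0.37 (adjusted p = 0.948), with 12.17, 12.08 and 11.22 in WT and 10.61, 11.08 and 11.90 in Glo1+/-. In aorta the libraries labelled 3 overlap with the other genotype: 11.90 in the library labelled Glo1+/- aorta 3 and 11.22 in the library labelled WT aorta 3. The genotype label of the second is in doubt as well. Its Glo1 value lies nearer to Glo1+/- aorta 1 and 2 than to WT aorta 1 and 2. Across probes, which are not independent replicates, it correlated at 0.985 and 0.986 with the former and 0.983 and 0.979 with the latter. Such correlations do not tell the genotypes apart, as WT aorta 1 had 0.990 with both WT aorta 2 and Glo1+/- aorta 1. The doubt thus rests on the Glo1 value, and this library also carries thymocyte transcripts (Cd3d at 12.02). Both labels were kept, and without the library labelled WT aorta 3 the Glo1 change in aorta was -0.93 (adjusted p = 0.983). The fold of Glo1+/- over WT was 0.54 in adipose tissue, liver and kidney and 0.65 in aorta. Within slide 2 the Glo1 change in kidney was -0.96 (adjusted p = 0.206) and no longer passed. Nor did it pass without WT kidney 1 (adjusted p = 0.054), WT kidney 2 (0.087), Glo1+/- kidney 1 (0.088) or Glo1+/- kidney 2 (0.066). Over the 4 tissues the average change was -0.82 ± 0.13 (adjusted p = 0.0066), and -0.91 ± 0.11 (adjusted p = 2.12e-04) without the library labelled Glo1+/- aorta 3. The 3 probes of Nnt, a mitochondrial transhydrogenase gene with a known deletion in C57BL/6J, lay at the floor with group means of 8.07 to 8.20.

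**Figure D1:**
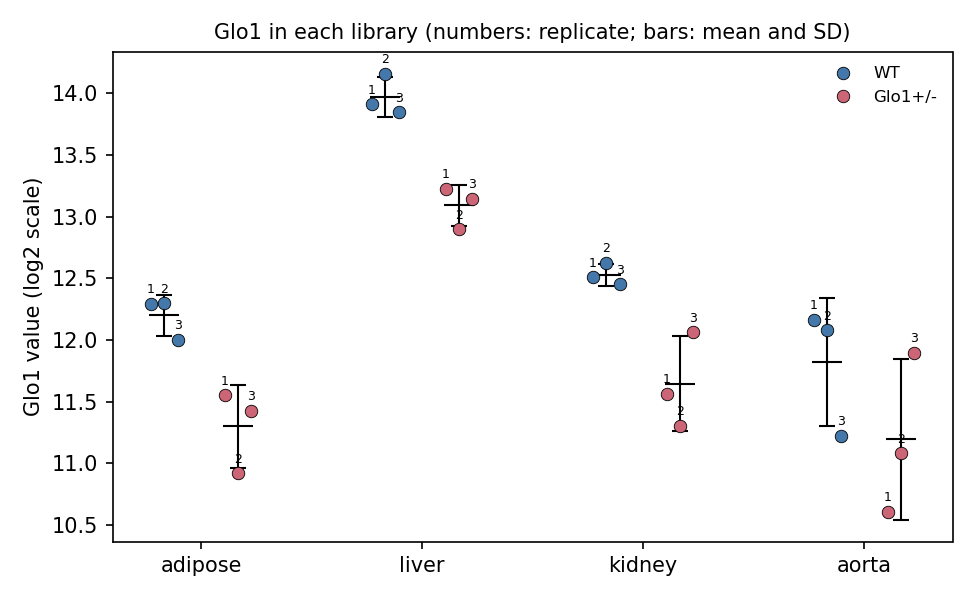
Value of the Glo1 probe on the log2 scale (vertical axis) in each library of each tissue (horizontal axis), with points numbered by replicate and bars for the mean and SD of 3 libraries. Glo1+/- liver lies between 12.90 and 13.22 and WT liver between 13.85 and 14.16, while in aorta the libraries labelled 3 lie at 11.22 (WT) and 11.90 (Glo1+/-).

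Several libraries carried transcripts of other tissues. Ucp1, the uncoupling protein of brown fat, read 14.57 to 14.82 in 5 aorta libraries and 8.14 in the library labelled Glo1+/- aorta 3. That library also had the lowest Myh11, a smooth muscle myosin, at 9.13 against 11.12 to 12.15, and the highest Lep, the fat hormone leptin, at 14.73 against 9.21 to 11.40. Thymocyte genes were bright in the library labelled WT aorta 3, with Cd3d at 12.02 and Rag1 at 11.37, where the other aorta libraries had 8.20 to 8.53 and 8.14 to 8.33. Skeletal muscle actin Acta1 read 14.16 in WT aorta 2. In adipose tissue the hepatocyte list had medians of 11.96, 11.66 and 9.32 in WT and 9.94, 9.01 and 8.31 in Glo1+/-. Kidney tubule genes were bright in the adipose libraries numbered 1, with Slc34a1 at 13.29 in WT and 14.36 in Glo1+/-. Epididymal genes were bright in Glo1+/- adipose 3, with Lcn8 at 14.83 and Spag11b at 14.19, where the other adipose libraries had 8.15 to 8.27 and 8.06 to 8.20. Xist, which is expressed from the inactive X chromosome of females, lay at 8.03 to 8.25 on both probes in all 24 libraries labelled female. Eif2s3y, on the Y chromosome, read 10.34 to 11.28. Other Y-linked genes lay closer to the floor, with Kdm5d at 8.40 to 8.81, Uty at 8.27 to 8.58 and Usp9y at 8.04 to 8.15. Of 14 male-biased liver genes 11 had a liver mean over 1 log2 unit above the same probe's lowest mean in another tissue, with Cyp4a12a at 13.26 to 13.84 and Mup20 at 13.29 to 13.65 in the 6 liver libraries. Slco1a1 (liver mean 8.20), Ugt2b38 (8.10) and Moxd1 (8.35) did not.

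**Figure D2:**
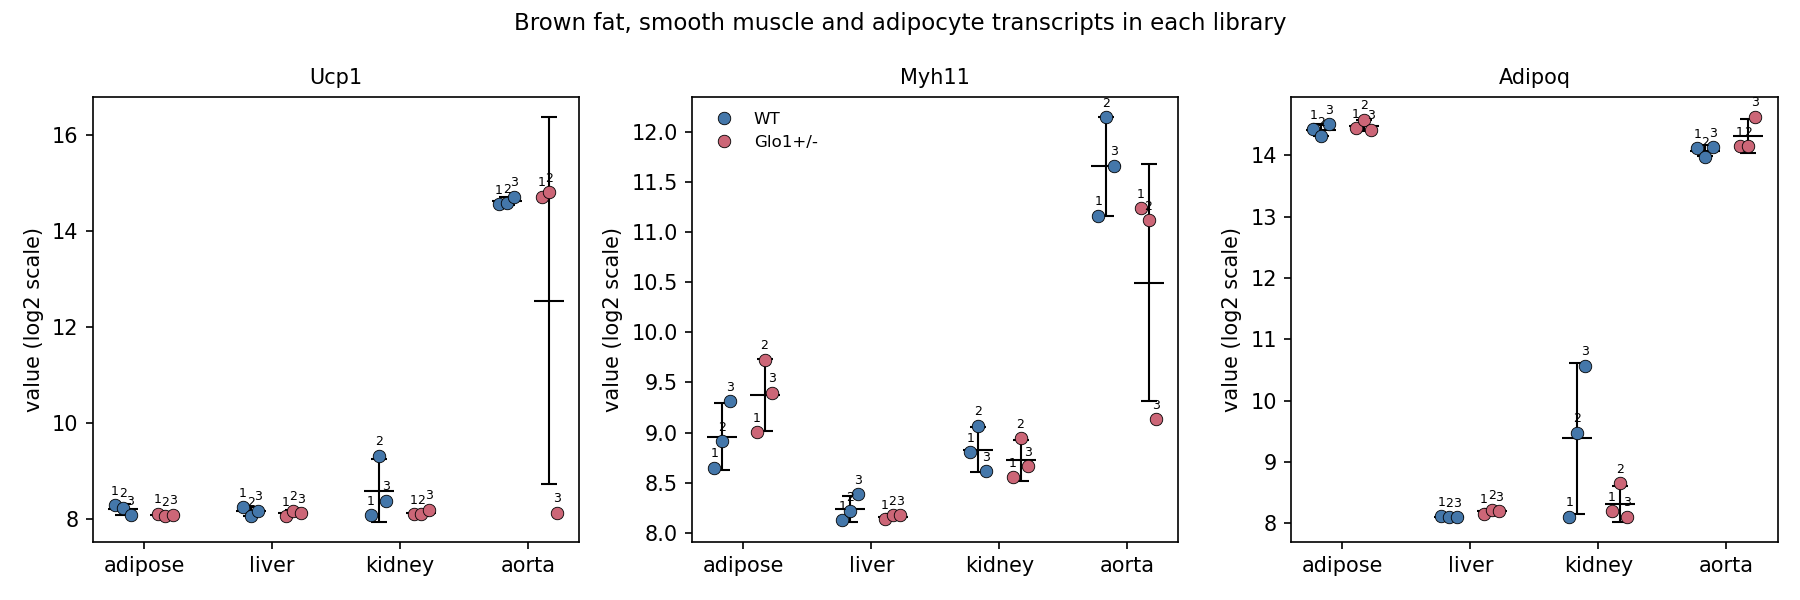
Values on the log2 scale (vertical axes) of Ucp1, Myh11 and Adipoq, transcripts of brown fat, smooth muscle and adipocytes, in each library of each tissue, with points numbered by replicate and bars for the mean and SD of 3 libraries. The library labelled Glo1+/- aorta 3 lies at 8.14 for Ucp1 and 9.13 for Myh11, apart from the other 5 aorta libraries.

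In gonadal adipose tissue a single gene passed the test. Tuba1a, an alpha tubulin of the cytoskeleton, fell from 13.70 ± 0.11 to 12.13 ± 0.20 (log2 change -1.58 ± 0.12, adjusted p = 0.026, n = 3 per group). At an unadjusted p under 0.05 stood 2927 probes, where 1284.9 would be expected without any change. In 23.5% of the probes above the median of the tissue the groups did not overlap, where chance gives 10%. None of the other genes named here passed. Among them the largest differences upward were Cldn11, a tight junction claudin (2.3 ± 0.31, adjusted p = 0.122), Chac1, which degrades glutathione (1.56 ± 0.20), and Slc27a1, a fatty acid transporter (1.45 ± 0.17, adjusted p = 0.106). Enc1 (1.16 ± 0.17), Fbxo21 (1.04 ± 0.12), the glutathione transferase Gstt2 (1.03 ± 0.14), the taurine transporter Slc6a6 (0.89 ± 0.11) and the epoxide hydrolase Ephx2 (0.83 ± 0.10) followed. Downward were the transcriptional repressor Bcl6 (-1.40 ± 0.17), Igfals, which binds insulin-like growth factors in plasma (-1.17 ± 0.12), Nrep (-1.0 ± 0.12), the chemokine Ccl7 (-0.77 ± 0.10) and Clec4b1 (-0.69 ± 0.09). Leptin was at -0.38 ± 0.09 (adjusted p = 0.279), Ccl2 at -0.42 ± 0.06 (adjusted p = 0.122), Adipoq at 0.07 ± 0.07 and Ucp1 at -0.12 ± 0.05. Tuba1a did not pass without WT 1 (adjusted p = 0.367), WT 2 (0.220) or Glo1+/- 3 (0.150), and without WT 3 or Glo1+/- 2 the count rose to 176 and 10 probes. With the replicate number as a block 49 probes passed, 13 higher and 36 lower, Tuba1a among them.

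Lipid synthesis genes shifted downward together in adipose tissue by camera at the preset correlation. Hepatocyte genes fell in the same libraries, and among probes not brighter in liver or kidney the fatty acid synthesis call was lost, as given below. All 11 list calls of this tissue were lost with an estimated correlation (adjusted p = 0.957 for each). The fatty acid and triglyceride synthesis list had a median of -0.29 (adjusted p = 4.66e-04; 21 of 27 measured genes lower, 0 called over all probes, 10 lower adjusted over the list alone), with Dgat2, the last step of triglyceride synthesis, at -0.51 ± 0.06. Mogat2 (-0.60 ± 0.11), Scd2 (-0.46 ± 0.09) and Fasn (-0.46 ± 0.09) had the same sign, and Lpin1 (0.68 ± 0.25) the opposite. Cholesterol synthesis had a median of -0.36 (adjusted p = 3.09e-05; 15 of 18 lower, 5 adjusted over the list alone), with Fdps at -1.06 ± 0.26, Insig1 at -0.63 ± 0.11, Pmvk at -0.37 ± 0.08, Sc5d at -0.32 ± 0.08 and Stard4 at 0.07 ± 0.16. Extracellular matrix and fibrosis (-0.18, adjusted p = 0.0015; 28 of 42 lower, 8 lower and 2 higher adjusted over the list alone) included Vim (-0.78 ± 0.10), the collagen chaperone Serpinh1 (-0.82 ± 0.12), Col3a1 (-0.68 ± 0.15), Pcolce (-0.42 ± 0.10) and, against it, Thbs2 (0.95 ± 0.25). Cell cycle (-0.10, adjusted p = 4.33e-05; 25 of 29 lower, 3 adjusted over the list alone) included Cdkn2c (-0.81 ± 0.12), Prc1 (-0.40 ± 0.09), Tk1 (-0.37 ± 0.07), Tyms (-0.28 ± 0.08) and Ccnd1 (0.44 ± 0.22). Macrophage genes (-0.17, adjusted p = 3.94e-04; 26 of 31 lower) included lysozyme Lyz2 (-0.65 ± 0.17), Fcer1g (-0.45 ± 0.15), Retnla (-0.34 ± 0.10), Lgals3 (-0.32 ± 0.09) and Clec10a (0.38 ± 0.12). Endothelial genes shifted upward (0.18, adjusted p = 0.0058; 19 of 26 higher, 6 adjusted over the list alone), with Eng at 0.80 ± 0.13, Plvap at 0.78 ± 0.14, Flt1 at 0.63 ± 0.13, Sox17 at 0.51 ± 0.12 and Ets1 at -0.21 ± 0.12. Clock genes also shifted upward (0.26, adjusted p = 0.026; 14 of 17 higher, 5 higher and 1 lower adjusted over the list alone), with Per2 at 1.40 ± 0.37, Usp2 at 0.99 ± 0.20, Fkbp5 at 0.96 ± 0.28, Tef at 0.69 ± 0.19 and Clock at -0.43 ± 0.14.

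The hepatocyte list had the largest shift in adipose tissue, -1.68 (adjusted p = 7.24e-07; 28 of 31 lower), with Cyp3a11 at -2.38 ± 0.68, Vtn at -1.57 ± 0.54, Hal at -1.54 ± 0.49 and Cyp2e1 at 0.26 ± 0.09. The P450 and conjugation list, which shares liver genes, moved with it (-0.86, adjusted p = 0.021; Cyp2f2 -1.51 ± 0.50, Cyp1a2 -1.31 ± 0.42, Cyp2c29 -0.31 ± 0.10). So did bile acid and lipoprotein metabolism (-0.46, adjusted p = 0.0045; Apoc1 -0.59 ± 0.21, Angptl8 -0.48 ± 0.14, Apoa5 -0.46 ± 0.16, Mttp -0.18 ± 0.06, Abcg1 0.64 ± 0.11) and acute phase (-0.45, adjusted p = 0.0023; Crp -2.04 ± 0.53, Orm1 -0.95 ± 0.26, Hamp2 -0.71 ± 0.22, Lbp -0.57 ± 0.17). Lcn2, on the acute phase list, stood at 3.13 ± 0.97 (adjusted p = 0.345) with an SD of 2.35 in Glo1+/-. In these 4 lists 0 members were called over all probes, and adjusted over the list alone 1 passed, Abcg1 upward. Among the probes not brighter in liver or kidney, an alternative chosen after seeing the data, the matrix, cell cycle, macrophage and endothelial calls were kept. Fatty acid synthesis was not (adjusted p = 0.214), and cholesterol synthesis, P450 and hepatocyte genes were too few there to test. The clock list had 0.15 (adjusted p = 0.980), and the bile acid and lipoprotein list shifted up (0.33, adjusted p = 0.028). The acute phase median was -0.035 (adjusted p = 0.862). Leaving out WT 1 ended the calls for bile acid (adjusted p = 0.071), P450 (0.317), clock (0.057) and endothelial genes (0.114). Bile acid was lost without Glo1+/- 3 (0.101), P450 without Glo1+/- 2 (0.073) or 3 (0.121), and clock without Glo1+/- 2 (0.077). With the replicate block the kidney tubule list, whose median of 0.42 had an adjusted p of 0.056, was called upward (adjusted p = 4.93e-04), beside the tubule genes of the libraries numbered 1.

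In liver 169 probes passed, 81 higher and 88 lower in Glo1+/-, for 63 and 77 genes and 11 probes without a gene name. Among them were 5 higher genes of fatty acid oxidation, 4 lower genes of fatty acid synthesis and 4 lower matrix genes. The largest rise was Lcn2, the lipocalin of the acute phase response (9.23 ± 0.91 in WT, 11.29 ± 0.26 in Glo1+/-, log2 change 2.07 ± 0.31, adjusted p = 0.0098, n = 3 per group), followed by the fatty acid hydroxylase Cyp4a31 (1.71 ± 0.20, adjusted p = 0.0031). Usp2 (1.48 ± 0.30), the translation repressor Eif4ebp3 (1.43 ± 0.26), the clock repressor Ciart (1.21 ± 0.19), the odorant binding protein Obp2a (1.20 ± 0.22), and Lpin1, a phosphatidate phosphatase (1.14 ± 0.19), rose as well. So did Alas1, the rate-limiting enzyme of haem synthesis (1.06 ± 0.22), the xenobiotic receptor Nr1i3 (0.98 ± 0.11), the glutathione transferase Gstp2 (1.20 ± 0.13) and the lipid droplet protein Plin4 (0.98 ± 0.13). Gpcpd1, which cleaves glycerophosphocholine, had the smallest adjusted p (6.57e-05) with a rise of 1.25 ± 0.09. The largest falls were the immediate early gene Egr1 (-1.85 ± 0.37), Bcl6 (-1.77 ± 0.23), the tubulin Tubb2b (-1.33 ± 0.28), the protease inhibitor Slpi (-1.10 ± 0.22), Chrna4 (-1.10 ± 0.23) and Cyp2c55 (-1.08 ± 0.13). Cxadr (-0.93 ± 0.13), annexin Anxa2 (-0.86 ± 0.10), Gadd45g (-0.84 ± 0.13), Gsta1 (-0.83 ± 0.18) and Insc (-0.82 ± 0.11) fell too. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.49 ± 0.20 (adjusted p = 0.364), Scd1 at -0.30 ± 0.08 (0.116), Fasn at -0.36 ± 0.13 (0.274), Pck1 at 0.29 ± 0.10 (0.261) and G6pc at -0.13 ± 0.26 (0.895), and none of these passed. Within slide 2, where only WT liver 3 stands against 3 Glo1+/- libraries and is assumed to vary like them, 1379 probes passed, 528 higher and 851 lower. The count was 110 without WT 1, 67 without WT 2, 695 without WT 3, and 29, 30 and 22 without Glo1+/- 1, 2 and 3.

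Fatty acid oxidation and PPAR alpha targets had the smallest preset-correlation p of the liver lists (median 0.24, adjusted p = 1.38e-09; 24 of 30 measured genes higher, 5 called up, 15 up and 1 down adjusted over the list alone; adjusted p = 0.422 with an estimated correlation). Cyp4a31, Eci2 (0.64 ± 0.10), the hormone Fgf21 (0.58 ± 0.10) and the carnitine carrier Slc25a20 (0.57 ± 0.10) rose, and Pdk4 stood at -0.55 ± 0.17 (adjusted p = 0.190). Fatty acid and triglyceride synthesis shifted down (-0.26, adjusted p = 0.0035; 4 called down and 1 up, 14 down and 3 up adjusted over the list alone; adjusted p = 0.432 with an estimated correlation). Its members Elovl6 (-0.74 ± 0.13), Acly (-0.66 ± 0.09), Me1 (-0.64 ± 0.11) and Acaca (-0.51 ± 0.10) fell, and Lpin1 rose. Within slide 2 its median was -0.13 (adjusted p = 0.568), and without WT 2 the adjusted p was 0.068, while fatty acid oxidation had 0.19 (adjusted p = 8.10e-04) there, with a single WT library. Endothelial genes shifted down (-0.29, adjusted p = 1.96e-07; 23 of 26 lower, 1 called, 16 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation), with Ets1 (-0.58 ± 0.12) called, Flt1 at -0.50 ± 0.11, Icam2 at -0.49 ± 0.13, Eng at -0.42 ± 0.11 and Bmx at 0.08 ± 0.07. Matrix genes shifted down (-0.18, adjusted p = 1.53e-07; 31 of 34 lower, 4 called, 9 adjusted over the list alone; adjusted p = 0.422 with an estimated correlation), led by Sparc (-0.72 ± 0.13), Acta2 (-0.69 ± 0.13), Col4a2 (-0.66 ± 0.10) and Col4a1 (-0.65 ± 0.12), with Fmod at 0.04 ± 0.07. Within slide 2 these medians were -0.39 (adjusted p = 4.56e-07) for endothelium and -0.23 (adjusted p = 0.0012) for matrix.

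Immediate early genes in liver shifted down (-0.32, adjusted p = 2.02e-04; 13 of 17 lower, 3 called, 9 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation). Egr1, Gadd45g and Jun (-0.48 ± 0.09) fell, with Zfp36 at -0.54 ± 0.15 and Ccn2 at 0.13 ± 0.26. Clock genes shifted up (0.33, adjusted p = 0.0071; 3 called up and 1 down, 9 up and 4 down adjusted over the list alone; adjusted p = 0.422 with an estimated correlation). Usp2, Ciart (1.09 ± 0.18 on the list's probe) and Per1 (0.57 ± 0.10) rose, Nfil3 (-0.77 ± 0.15) fell, and Fkbp5 stood at 1.01 ± 0.24 (adjusted p = 0.081). Acute phase genes shifted up (0.072, adjusted p = 0.0071; 2 called, 9 up and 2 down adjusted over the list alone; adjusted p = 0.541 with an estimated correlation). Lcn2 and Serpina3n (0.58 ± 0.10) rose, and Saa1 (1.23 ± 0.28), Saa2 (1.38 ± 0.34) and Hamp2 (-1.25 ± 0.28) did not pass. The adipocyte list (0.079, adjusted p = 0.046; 2 called, 6 up and 2 down adjusted over the list alone; adjusted p = 0.432 with an estimated correlation) holds lipid droplet genes that liver also expresses, and Plin4 and the lipase Pnpla2 (0.53 ± 0.11) rose. Cidec (0.62 ± 0.19), Cebpb (0.29 ± 0.10) and Fabp5 (-0.32 ± 0.11) did not. Within slide 2 the medians were -0.35 for immediate early (adjusted p = 0.014), 0.16 for clock (0.135), 0.11 for acute phase (0.0039) and 0.038 for adipocyte genes (0.051). The acute phase call was lost without WT 2 (adjusted p = 0.105) or WT 3 (0.110), and the adipocyte call without WT 1 (0.075), WT 3 (0.133), Glo1+/- 1 (0.096) or Glo1+/- 3 (0.081).

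In kidney 98 probes passed, 53 higher and 45 lower, for 48 and 36 genes and 5 unnamed probes, and 9 of the higher genes are on the fatty acid oxidation list. Pck1, the rate-limiting enzyme of gluconeogenesis, rose by 1.11 ± 0.17 (8.95 ± 0.46 in WT, 10.06 ± 0.15 in Glo1+/-, adjusted p = 0.015, n = 3 per group). Cyp4a31 (1.10 ± 0.15, adjusted p = 0.011), the lipase inhibitor Angptl4 (1.07 ± 0.17) and Cyp2d12 (0.93 ± 0.08, the smallest adjusted p, 5.96e-04) rose too. Further rises were Acaa2 (0.75 ± 0.14) and Ehhadh (0.68 ± 0.11) of beta oxidation, the acyl-CoA thioesterase Acot3 (0.72 ± 0.12), the carbonic anhydrase Car9 (0.74 ± 0.12), the bile acid receptor Nr1h4 (0.70 ± 0.08), Rdh16 (0.67 ± 0.10), Gsta2 (0.67 ± 0.10) and Ftcd (0.66 ± 0.12). Egr1 fell by 1.52 ± 0.15 (adjusted p = 0.0015), Car3 by 1.24 ± 0.15, Bcl6 by 1.23 ± 0.23 and the transferrin receptor Tfrc by 1.08 ± 0.12. Serpinf1 (-0.93 ± 0.17), the sodium-calcium exchanger Slc8a1 (-0.87 ± 0.13), the integrin Itgb6 (-0.86 ± 0.10), Ldc1 (-0.80 ± 0.13), the nucleotidase Nt5e (-0.72 ± 0.11), the insulin-degrading enzyme Ide (-0.67 ± 0.10) and the nucleoside transporter Slc29a3 (-0.65 ± 0.11) fell too. Adipoq, an adipocyte transcript, read 8.11, 9.48 and 10.57 in WT and 8.20, 8.66 and 8.11 in Glo1+/- kidney, beside the fat genes Car3 and Serpinf1. The injury markers Havcr1 (0.15 ± 0.10, adjusted p = 0.659) and Lcn2 (0.14 ± 0.12, adjusted p = 0.759) and the tubule gene Umod (0.04 ± 0.07, adjusted p = 0.901) did not pass. Within slide 2, where Glo1+/- kidney 1 stands alone against 3 WT libraries, 20 probes passed, 14 higher and 6 lower. The count was 46 without WT 1, 32 without WT 2, and 41, 46 and 19 without Glo1+/- 1, 2 and 3.

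Of 30 measured fatty acid oxidation and PPAR alpha genes in kidney, 26 were higher, 9 called up and 0 down, and 21 up and 1 down adjusted over the list alone (median 0.41, adjusted p = 1.49e-15; adjusted p = 0.341 with an estimated correlation; fry 0.041). Cpt2 (0.64 ± 0.09), Eci2 (0.61 ± 0.09) and Acaa1b (0.52 ± 0.08) rose with Cyp4a31, and the brown fat gene Cidea stood at -0.58 ± 0.25. Gluconeogenesis and insulin signalling shifted up (0.078, adjusted p = 0.040; Pck1 called, 8 up and 1 down adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), with Slc37a4 at 0.49 ± 0.10, Fbp2 at 0.48 ± 0.11, Fbp1 at 0.32 ± 0.07 and Igf1 at -0.28 ± 0.07. The unfolded protein response shifted down (-0.17, adjusted p = 1.55e-04; 3 called down, 9 down and 1 up adjusted over the list alone; adjusted p = 0.341 with an estimated correlation; fry 0.041). The chaperones and pore subunit Calr (-0.54 ± 0.10), Sec61b (-0.51 ± 0.09) and Pdia3 (-0.48 ± 0.07) fell, with Hsp90b1 at -0.55 ± 0.11 and Atf4 at 0.23 ± 0.08. Clock genes shifted up (0.19, adjusted p = 1.93e-04; Ciart called at 0.57 ± 0.11, 7 up and 1 down adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), with Tsc22d3 at 0.83 ± 0.19, Per1 at 0.69 ± 0.15, Dbp at 0.61 ± 0.15 and Clock at -0.37 ± 0.09. Matrix genes shifted down (-0.080, adjusted p = 1.47e-04; Col4a1 called at -0.55 ± 0.09, 7 adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), with Sparc at -0.41 ± 0.10, Col4a2 at -0.35 ± 0.09, Col15a1 at -0.33 ± 0.07 and Mmp14 at 0.09 ± 0.07.

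Smaller shifts in kidney were upward for NRF2 and glutathione (0.073, adjusted p = 0.021; Gsta2 called, 2 adjusted over the list alone) and for the cell cycle (0.073, adjusted p = 0.0055; 0 called, 4 up and 1 down adjusted over the list alone). They were downward for cholesterol synthesis (-0.094, adjusted p = 0.011; 17 of 18 lower, 0 called, 2 adjusted over the list alone) and for inflammatory cytokines and chemokines (-0.058, adjusted p = 0.040; 0 called, 0 adjusted over the list alone). With an estimated correlation the adjusted p of these lists was 0.426, 0.426, 0.523 and 0.565. Members that did not pass were Cat (0.46 ± 0.10), Gstm1 (0.43 ± 0.15), Cbr1 (0.26 ± 0.09) and Cbr3 (-0.10 ± 0.07), and Ccnd1 (0.34 ± 0.08), Uhrf1 (0.28 ± 0.07), Mcm5 (0.27 ± 0.08), Stmn1 (0.18 ± 0.06) and Ccnd2 (-0.22 ± 0.07). Likewise Msmo1 (-0.51 ± 0.14), Fdps (-0.40 ± 0.14), Idi1 (-0.35 ± 0.07), Dhcr7 (-0.21 ± 0.08) and Stard4 (0.11 ± 0.09), and Il15 (-0.31 ± 0.10), Cxcl9 (-0.25 ± 0.07), Ccl4 (-0.22 ± 0.08), Cxcl1 (-0.21 ± 0.08) and Nfkbia (0.08 ± 0.10), did not pass. Within slide 2 the median of NRF2 was 0.042 (adjusted p = 0.092), of cholesterol synthesis -0.13 (0.0027), of inflammatory genes -0.056 (0.536) and of the cell cycle 0.047 (0.103). There fatty acid oxidation had 0.43 (2.47e-19), gluconeogenesis 0.11 (0.015), the unfolded protein response -0.24 (5.08e-04), clock 0.28 (0.0044) and matrix -0.13 (4.86e-04). The NRF2 call was lost without WT 3 (adjusted p = 0.138) or Glo1+/- 3 (0.087), and cholesterol without WT 1 (0.061) or Glo1+/- 1 (0.072). Gluconeogenesis was lost without WT 1 (0.067), WT 2 (0.061) or Glo1+/- 1 (0.123). Inflammatory genes were lost without WT 2 (0.151), WT 3 (0.137), Glo1+/- 2 (0.101) or Glo1+/- 3 (0.150).

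In aorta 0 probes passed with limma (smallest adjusted p 0.948), and 917 had an unadjusted p under 0.05, fewer than the 1284.9 expected without change. That count was 2023 without the library labelled Glo1+/- aorta 3 and 3078 without both labelled 3. With all 6 libraries 10.4% of the probes above the median of the tissue had groups that did not overlap, where chance gives 10%. None of the genes named for aorta passed. The haem oxygenase Hmox1 stood at 0.94 ± 0.19, Per2 at 0.96 ± 0.23, Chac1 at 0.85 ± 0.19, the kinase Map3k6 at 0.71 ± 0.16, Pofut1 at 0.63 ± 0.11 and Smim41 at 0.58 ± 0.12 (n = 3 per group). Aadacl4 (0.31 ± 0.06) and Zfp598 (0.29 ± 0.06) were close to the floor. Downward stood the centromere histone Cenpa (-0.86 ± 0.22), E2f2 (-0.73 ± 0.18), Rpa3 (-0.58 ± 0.15), Fam110b (-0.54 ± 0.14), Rassf2 (-0.47 ± 0.12), the clock gene Arntl (-0.45 ± 0.10), Igdcc4 (-0.40 ± 0.10) and Gpsm2 (-0.20 ± 0.05). Smooth muscle Myh11 was at -1.16 ± 0.55, Acta2 at -0.55 ± 0.24, Vcam1 at -0.02 ± 0.41 and Ucp1 at -2.07 ± 1.59. These include the library labelled Glo1+/- aorta 3, which had the lowest Myh11 and Ucp1 of the aorta libraries. The falls of Myh11 and Ucp1 are therefore not read as an effect of genotype. Without both libraries labelled 3, an alternative chosen after seeing the data, 349 probes passed, 200 higher and 149 lower. Glo1 then fell by 1.28 (adjusted p = 0.0016). The libraries left out are those whose Glo1 values overlap with the other genotype, so the choice itself enlarged that fall and its p is no support. With 1 WT or Glo1+/- library left out at a time the count stayed at 0.

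Clock, mast cell, P450, immediate early and smooth muscle genes of aorta were called with all 6 libraries, without the library labelled Glo1+/- aorta 3 and without both labelled 3. With an estimated correlation the adjusted p was 0.257 for mast cell and P450 genes and 0.548 for clock, immediate early and smooth muscle genes. Clock genes had 0.29 (adjusted p = 2.74e-04; 2 up and 1 down adjusted over the list alone), then 0.37 (adjusted p = 3.87e-04) and 0.55 (adjusted p = 1.54e-06), with Per2 at 1.06 ± 0.28 on the list's probe, Tsc22d3 at 0.85 ± 0.29, Ciart at 0.71 ± 0.19 and Dbp at 0.60 ± 0.23. Mast cell genes had 0.34 (adjusted p = 5.07e-07; 9 of 9 higher, 1 adjusted over the list alone), 0.30 and 0.34, with the mast cell proteases Cma1 at 0.48 ± 0.16 and Tpsb2 at 0.41 ± 0.11, Srgn at 0.36 ± 0.13 and Fcer1a at 0.26 ± 0.09. P450 and conjugation had 0.29 (adjusted p = 2.74e-04), 0.34 and 0.38, with Sult1a1 at 0.93 ± 0.28, Cyp2e1 at 0.82 ± 0.34, Cyp2f2 at 0.60 ± 0.31, Fmo5 at 0.36 ± 0.12 and Fmo1 at -0.28 ± 0.28. Immediate early genes had -0.24 (adjusted p = 1.81e-04), -0.20 and -0.36, with Egr1 at -1.65 ± 0.47, Ccn2 at -0.73 ± 0.26, Dusp1 at -0.54 ± 0.20, Fosb at -0.31 ± 0.12 and Socs3 at 0.30 ± 0.21. Smooth muscle contractile genes had -0.48 (adjusted p = 5.07e-07; 24 of 28 lower), -0.18 and -0.25, with Mrvi1 at -0.79 ± 0.33, Actn1 at -0.56 ± 0.23, Tpm1 at -0.54 ± 0.19 and Ptk2b at 0.12 ± 0.13. Adjusted over all probes 0 members of any list were called in aorta. Adjusted over the list alone, the 3 clock genes and 1 mast cell gene given were the only ones in the called lists.

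Of the other 12 called aorta lists, 3 were still called in the same direction without the library labelled Glo1+/- aorta 3 (NRF2, cell cycle and macrophage). In that library the list medians stood at 8.16 for brown fat (10.28 to 10.53 in the others) and 10.26 for macrophages (8.77 to 9.07). Brown and beige adipocyte genes had -0.96 (adjusted p = 0.0010; Acot11 -1.68 ± 1.22, Cox7a1 -1.77 ± 1.30, Ntrk3 -0.96 ± 0.40, Ppargc1b -0.81 ± 0.46, Dio2 0.08 ± 0.06). Oxidative phosphorylation had -0.27 (adjusted p = 1.63e-07; Ndufb2 -0.48 ± 0.34, Ndufa8 -0.44 ± 0.28, Atp5g2 -0.42 ± 0.30, Ndufb11 -0.28 ± 0.20, Atp5j 0.09 ± 0.18), and glycolysis had -0.25 (adjusted p = 0.017; Eno3 -0.94 ± 0.60, Pfkm -0.85 ± 0.33, Pfkfb2 -0.25 ± 0.14, Pgk1 -0.14 ± 0.06, Pfkfb3 0.11 ± 0.08). Without that library their medians were 0.093 (adjusted p = 0.0080, called upward), 0.042 (0.021, called upward) and 0.044 (0.298). Skeletal and heart muscle had -1.03 (adjusted p = 2.30e-07; Ckm -1.40 ± 0.68, Tnnt1 -1.03 ± 0.57, Myl1 -0.49 ± 0.16, Ldb3 -0.46 ± 0.25) beside the muscle genes of WT aorta 2. It had -1.04 (adjusted p = 4.41e-04) without WT aorta 2 and -0.22 (0.196) without the library labelled Glo1+/- aorta 3. Macrophage genes had 0.54 (adjusted p = 1.63e-07; Lyz2 1.09 ± 0.46, Clec10a 0.85 ± 0.33, Cd163 0.76 ± 0.30, Cd14 0.62 ± 0.26, Timd4 -0.07 ± 0.07), and 0.11 (adjusted p = 0.024) without the latter library. Adipocyte genes had 0.23 (adjusted p = 6.49e-04; G0s2 0.82 ± 0.28, Cidec 0.51 ± 0.23, Acvr1c 0.42 ± 0.17, Fabp4 0.29 ± 0.13, Ebf2 -0.35 ± 0.17). Inflammatory genes had 0.16 (adjusted p = 0.0017; Ccl8 0.78 ± 0.37, Ccl6 0.77 ± 0.26, Cxcl13 0.76 ± 0.26, Il18 0.44 ± 0.21, Cxcl16 -0.16 ± 0.17) and acute phase 0.31 (adjusted p = 1.24e-04; Saa3 1.00 ± 0.38, Orm1 0.33 ± 0.16, Orm2 0.30 ± 0.13, Itih4 -0.19 ± 0.17). Endothelial genes had 0.12 (adjusted p = 0.013; Robo4 0.63 ± 0.30, Ednrb 0.61 ± 0.25, Gpihbp1 0.58 ± 0.22, Cdh5 0.25 ± 0.14, Ets1 -0.43 ± 0.25), and hepatocyte genes 0.33 (adjusted p = 0.0044; Ass1 0.40 ± 0.27, Apoh 0.37 ± 0.24, Kng1 -0.31 ± 0.30). NRF2 had 0.11 (adjusted p = 0.046; Hmox1, Ephx1 0.45 ± 0.18, Gclm 0.41 ± 0.20, Mt1 0.30 ± 0.16, Gpx4 -0.27 ± 0.20), and the cell cycle -0.17 (adjusted p = 0.0028; Cenpa, Mad2l1 -0.31 ± 0.20, Rrm1 -0.30 ± 0.19, Cdc6 -0.18 ± 0.10, Cdkn2c 0.45 ± 0.33). With an estimated correlation every adjusted p of these 12 lists was between 0.548 and 0.754. Without that library hepatocyte genes were called downward (-0.18, adjusted p = 0.030), acute phase genes had -0.016 (0.672), and the adipocyte (0.055), inflammatory (0.459) and endothelial (0.076) calls were lost. NRF2 was lost without WT 1, WT 2, Glo1+/- 1 or Glo1+/- 2 (adjusted p from 0.062 to 0.164), and glycolysis without WT 1 (0.130). The cell cycle was lost without WT 3 (0.250), Glo1+/- 1 (0.054) or Glo1+/- 2 (0.148). Without WT 3, the library with bright thymocyte genes, the cell cycle median turned upward. Endothelium was lost without WT 3 (0.104) or Glo1+/- 1 (0.054). Hepatocyte genes were lost without WT 3 (0.104). Matrix genes, not called with all 6 libraries, shifted down without it (-0.21, adjusted p = 2.40e-05).

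**Figure D3:**
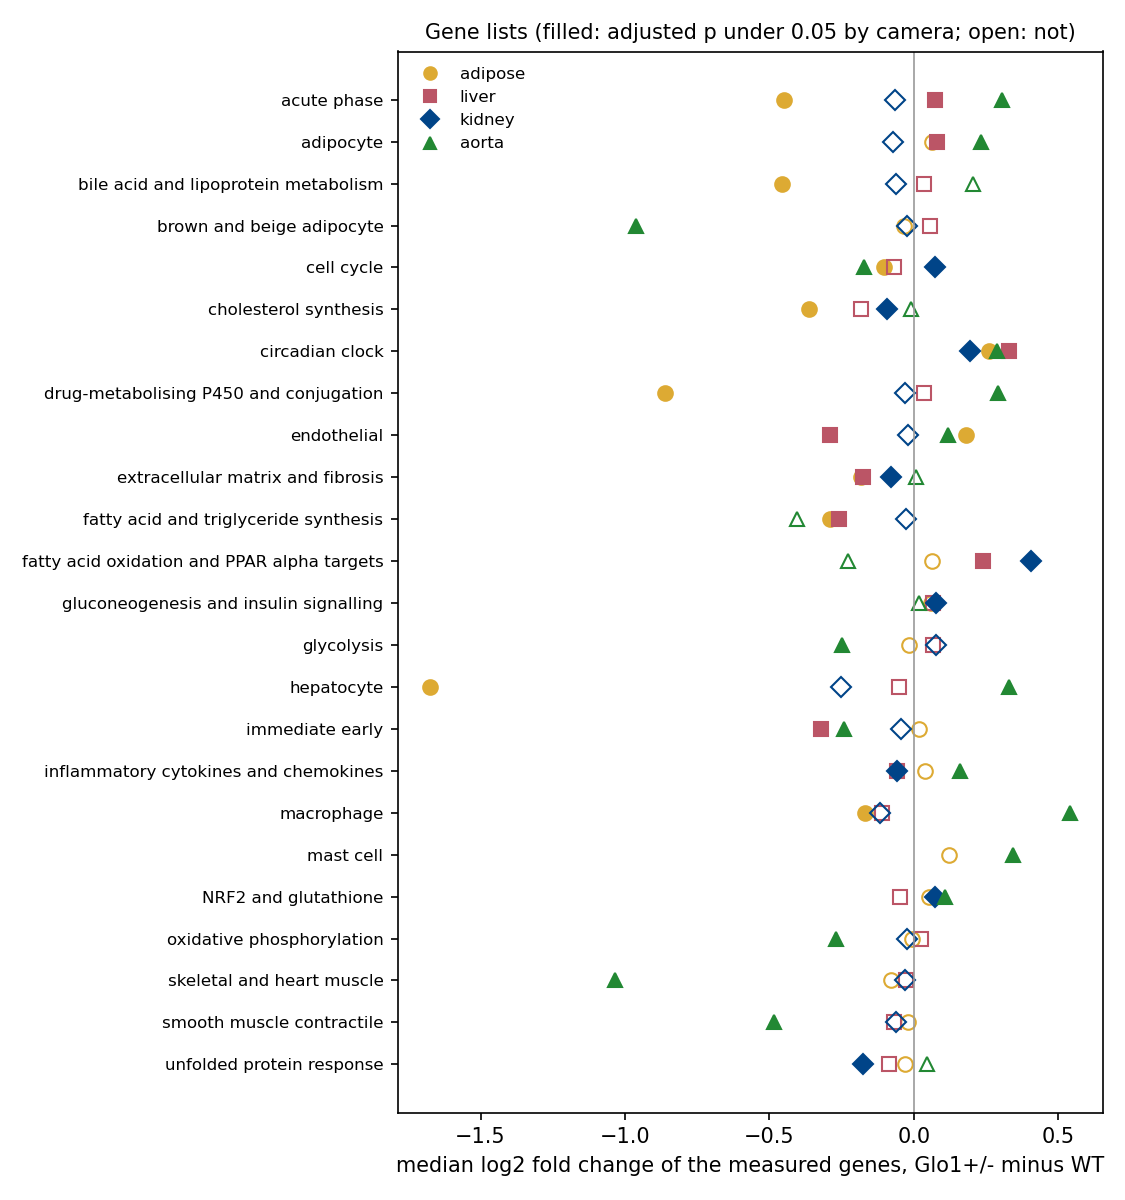
Median log2 fold change of the measured genes, Glo1+/- minus WT (horizontal axis), of each gene list called in at least 1 tissue (vertical axis), with filled symbols for an adjusted p under 0.05 by camera at the preset correlation. The clock list is filled in all 4 tissues, at 0.26 in adipose tissue, 0.33 in liver, 0.19 in kidney and 0.29 in aorta, and none of the calls held with an estimated correlation.

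Averaged over the 4 tissues, 69 probes passed, 45 higher and 24 lower, and for 48 of them the effect had the same sign in every tissue. Gstt2 (0.65 ± 0.07) and Gpcpd1 (0.33 ± 0.04) had the smallest adjusted p (8.29e-05), and Gpcpd1 owes its average to liver (1.25), as does Pde6c (0.54). The fatty acid transporter Slc27a1 (0.77 ± 0.09, adjusted p = 1.90e-04) rose with effects of 1.45, 0.56, 0.34 and 0.74 in adipose tissue, liver, kidney and aorta. Ide (-0.59 ± 0.07, adjusted p = 5.42e-04) fell, with effects of -0.54, -0.55, -0.67 and -0.59, and Bcl6 (-1.22 ± 0.16, adjusted p = 8.49e-04), with -1.40, -1.77, -1.23 and -0.48. Ciart (0.68 ± 0.10), Chac1 (0.72 ± 0.11), Cyp4a31 (0.75 ± 0.11), Pcsk4 (0.21 to 0.46 on 4 called probes, smallest adjusted p = 0.0036), Pde6c (0.14) and BC051142 (0.14) rose, and Cyb5b (-0.26) fell, although Chac1 was at -0.12 and Cyb5b at 0.02 in kidney. Gpcpd1 (-0.07 in adipose tissue) and Pde6c (-0.03 in kidney) also had 1 effect of the opposite sign. All 4 Pcsk4 probes had their largest effect in liver (0.73 to 0.87), and 3 of them rose in every tissue, while the probe of smallest adjusted p was at -0.03 in aorta. The clock list had a median of 0.30 with 3 members called up and 1 down. Without the library labelled Glo1+/- aorta 3, 405 probes passed, 202 higher and 203 lower, all 69 among them. The count was 6 without WT 1, 6 without WT 2, 284 without WT 3, and 33, 29 and 139 without Glo1+/- 1, 2 and 3 of every tissue. It was 6 without liver, 19 without kidney and 374 without aorta, and 0 when values were averaged over the tissues for each genotype and number, where 1967 probes had an unadjusted p under 0.05 with limma.

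**Figure D4:**
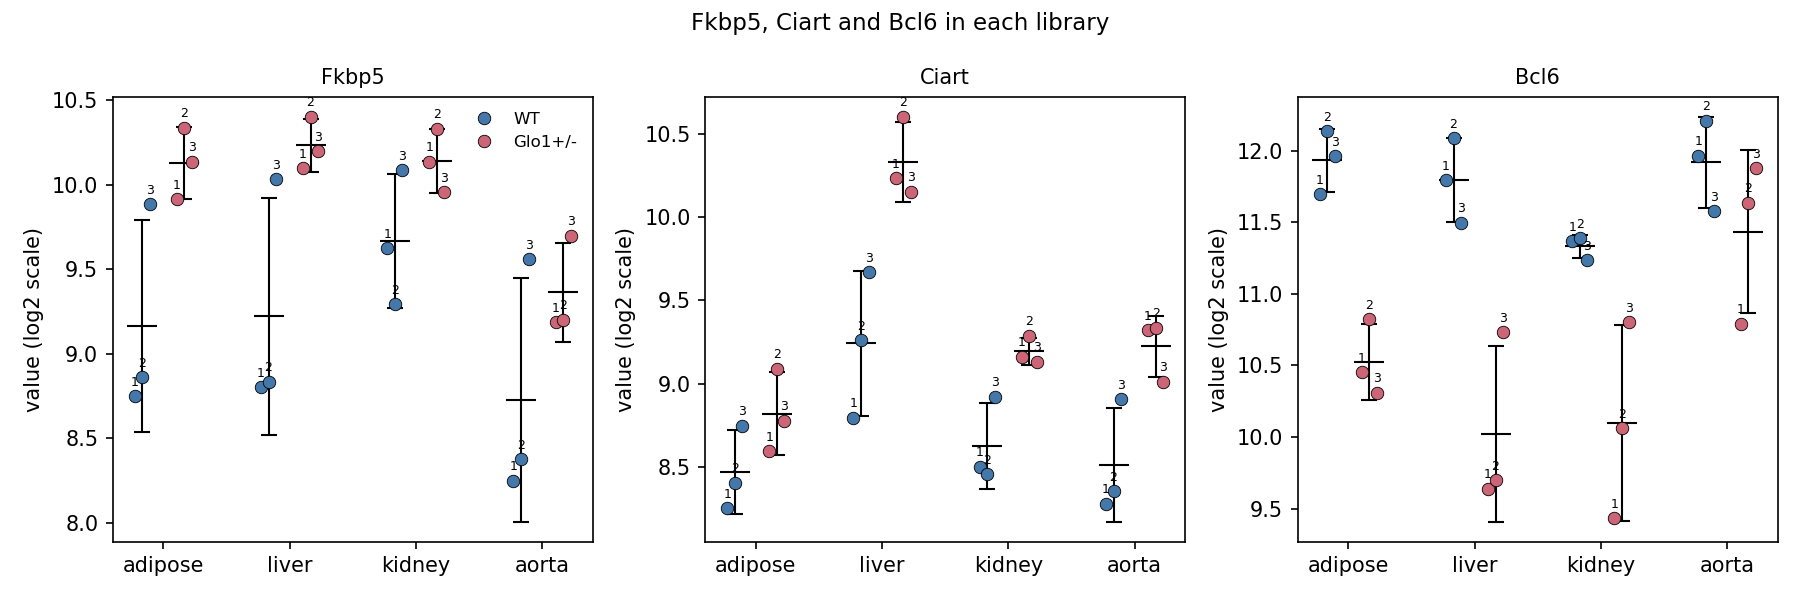
Values on the log2 scale (vertical axes) of the glucocorticoid-induced gene Fkbp5, the clock repressor Ciart and the repressor Bcl6 in each library of each tissue, with points numbered by replicate and bars for the mean and SD of 3 libraries. In every tissue WT 3 has the highest Fkbp5 and Ciart of the WT libraries, with Fkbp5 at 9.88, 10.03, 10.08 and 9.56 in adipose tissue, liver, kidney and aorta.

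Genes near Glo1 did not move with it as a group. On the list of proximal chromosome 17 around Glo1, 32 genes were measured with an average median of -0.012, and Glo1 alone was called. Fkbp5, also on the clock list, passed too without the library labelled Glo1+/- aorta 3 (0.73 ± 0.17, adjusted p = 0.036). With all libraries, members with an unadjusted p under 0.05 in the average effect were Fkbp5 (0.77 ± 0.17, adjusted p = 0.063), Abcg1 (0.21 ± 0.06, 0.127), Rrp1b (0.14 ± 0.05, 0.351), Srsf3 (-0.19 ± 0.08, 0.416) and Cmtr1 (-0.11 ± 0.05, 0.488). The Glo1 segment list has 2 measured genes and was too short to test, and there Btbd9 averaged 0.0041 ± 0.04, Dnah8 -0.04 ± 0.02 and Glp1r 0.02 ± 0.02.

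The genotype effect differed between tissues for 72 probes by the interaction test, in which data simulated with changes in liver only gave 33.2% false calls. Of the 12 with the smallest adjusted p, 11 had their largest effect in liver and effects between -0.15 and 0.23 in the other tissues, and Ntsr2 was opposite in adipose tissue (-0.42) and aorta (0.40). Gpcpd1 (adjusted p = 5.04e-07) was at 1.25 in liver and between -0.07 and 0.08 elsewhere, and the xenobiotic receptor Nr1i3 (adjusted p = 1.97e-04) at 0.98 in liver and between -0.11 and 0.02. Of these 11, the liver changes of Abca6 (0.32, adjusted p = 0.120), Akr1c6 (-0.30, 0.147), H2-Q10 (-0.41, 0.072) and Cphx1 (-0.37, 0.090) did not pass within liver alone. The group means of these genes and of Nr1i3, Pde6c, Cyp2c55 and Alb lay near the floor outside liver. A change could hardly show there. Effects of Glo1 itself were not shown to differ between tissues (adjusted p = 0.967). Without the library labelled Glo1+/- aorta 3, 320 probes passed, all 72 among them. The count was 11 without WT 1, 9 without WT 2, 290 without WT 3, 37 without Glo1+/- 1 and 167 without Glo1+/- 2, and 12, 0, 9 and 220 without adipose tissue, liver, kidney and aorta. Without liver 2222 probes had an unadjusted p under 0.05 with limma.

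Liver and kidney shared more calls than independent lists would. Of 7 shared higher probes (0.167 expected) the genes were Cyp4a31, Eci2, Slc25a20, Ciart, Gstt2, Eif4ebp3 and Pcsk4, and of 6 shared lower probes (0.154 expected) they were Bcl6, Egr1, Ide, Col4a1 and Glo1. Across 16593 genes, which are not independent replicates, the effects in liver and kidney correlated at 0.311 (Spearman 0.217). Of 100 regroupings 1 was as high, at the same value, and the lowest was -0.321. Exchanging the genotype labels of 1 tissue turns only the sign, so that grouping has a mirror image above 0.311. The regroupings treat the tissues as independent, and deviations of animals shared between tissues are not in them. The other 5 pairs gave 0.173 for adipose tissue and kidney, 0.052 for adipose tissue and liver, 0.049 for liver and aorta, 0.033 for kidney and aorta and -0.070 for adipose tissue and aorta. Of the 100 regroupings 19, 13, 26, 36 and 79 were as high. Without the library labelled Glo1+/- aorta 3 the pairs with aorta gave 0.162 for liver, 0.118 for adipose tissue and 0.098 for kidney.

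The lists called in no tissue include those closest to the function of Glo1. Dicarbonyl detoxification had its smallest adjusted p in kidney (0.199, median 0.099 over 17 genes), with Glo1 the only member called in liver and kidney. AGE receptors had theirs in liver (0.164, median -0.038 over 9 genes). This list also holds Glo1 itself, so its values are not of receptors alone. For the others the smallest adjusted p was 0.266 for heat shock, 0.346 for interferon response, 0.132 for sex-biased liver genes, 0.057 for lymphocytes, 0.293 for neutrophils and 0.126 for erythroid genes. It was 0.391 for Schwann cell and neuron, 0.703 for ovary, uterus and oviduct, 0.125 for mammary and other epithelium, 0.087 for mesothelium and 0.603 for exocrine pancreas. Kidney tubule had 0.056, glomerulus and podocyte 0.058, kidney injury 0.126 and proximal chromosome 17 around Glo1 0.214. By fry 3 lists passed, all in kidney: fatty acid oxidation up, and the unfolded protein response and erythroid genes down. Of the 45 list calls in the 4 tissues none held with an estimated correlation.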

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

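The tests of the label-set patterns and of the splits of single tissues by probe counts were chosen after the results were seen, and the splits by list counts and those of the average and the difference were planned. By the limma interaction test the genotype effect of Gpcpd1 differed between tissues (adjusted p = 5.04e-07), with effects of -0.07, 1.25, 0.06 and 0.08 in adipose tissue, liver, kidney and aorta. The interaction test gave Nr1i3 an adjusted p of 1.965e-04, with 0.98 in liver and -0.11 to 0.02 in the other tissues. It gave Pde6c, which encodes a cone phosphodiesterase, the same 1.965e-04, with 0.54 in liver and -0.03 to 0.04 elsewhere. Cyp2c55 also had 1.965e-04 in the interaction test, with -1.08 in liver and -0.07 to 0.04 elsewhere. A probe of Pcsk4 differed between tissues in the interaction test (adjusted p = 4.66e-04), with 0.73 in liver, and 1 other of its probes did too (0.038). A probe of the albumin gene Alb had an interaction adjusted p of 4.81e-04, with -0.67 in liver and -0.06, 0.01 and -0.03 in adipose tissue, kidney and aorta. Its liver means were 9.68 in WT and 9.01 in Glo1+/-. The change is of this probe and was not shown for albumin mRNA as a whole.

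The interaction test of the next 6 genes was planned, and no test in this part was chosen after the result was seen. For Gstp2 the limma interaction test gave an adjusted p of 0.0043, with 1.20 in liver and 0.23 in kidney. Ntsr2, a neurotensin receptor, had 0.0043 in the interaction test, with -0.42 in adipose tissue and 0.40 in aorta. The transporter gene Abca6 differed between tissues (interaction adjusted p = 0.0080), with 0.32 in liver. The steroid dehydrogenase Akr1c6 had an interaction adjusted p of 0.0094, with -0.30 in liver. The major histocompatibility gene H2-Q10 had the same interaction adjusted p of 0.0094, with -0.41 in liver. Cphx1 had an interaction adjusted p of 0.0108, with -0.37 in liver. Outside liver the group means of Abca6, Akr1c6, H2-Q10 and Cphx1 lay at 8.07 to 8.17, near the floor, where a change could hardly show. The group means of the Nr1i3, Pde6c, Cyp2c55 and Alb probes given above also lay near the floor outside liver. For these genes a lack of change in the other tissues was therefore not shown.

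Tests of the library labelled Glo1+/- aorta 3 were chosen after its white fat profile was seen. It lacks Ucp1, at 8.14, and correlates across probes, which are not independent replicates, at 0.995 with WT adipose 3 and at 0.924 to 0.934 with the other aorta libraries. A swap of labels within the set would put aorta transcripts in another library, but the highest Ucp1 among the 18 libraries labelled adipose, liver or kidney was 9.33, which argues against it. White in place of brown fat around this aorta would leave the vessel wall in place. Over the 28 measured smooth muscle contractile genes the library's median lay at -0.0018 from the adipose mean, where the 6 adipose libraries had -0.09 to 0.10 and the other 5 aorta libraries 0.66 to 1.05. This argues against a wall as large as in those aorta samples. RNA of WT adipose 3 on the array is the candidate explanation left, since the deviations of the library from the mean of the other adipose libraries correlated with those of WT adipose 3 at 0.831 across 12848 probes. With the other 5 adipose libraries that correlation was -0.27 to 0.33.

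Tests of the clock genes were chosen after the shift of their list was seen in all 4 tissues at the preset correlation. With an estimated correlation the list was called in 0 tissues. Its members Fkbp5, Ciart and Per1 have higher Glo1+/- means in each tissue, although Fkbp5 passed in none, and Bcl6 and Egr1 lower ones. Collection at another time or feeding state may explain this, and was not tested between the genotypes. Over the 17 clock genes same-numbered WT libraries of different tissues deviated together (mean r 0.597, exact permutation p = 0.0046, the smallest possible of 216). These deviations are from the WT mean of each tissue, so they cannot bear on the difference between the genotypes. Whether a number names 1 animal across tissues is not known, so the shared deviation may be of an animal or of a step of collection, and it does not show that the genotypes were collected at different times. For same-numbered Glo1+/- libraries a shared deviation was not shown (mean r -0.020, exact permutation p = 0.542), and without aorta they had 0.210 (exact permutation p = 0.083 of 36). Slide cannot act within adipose tissue or aorta, each on a single slide, where the clock medians were 0.26 and 0.29. Position on the slide goes with genotype in these tissues and stays open. In adipose tissue the median was 0.15 (adjusted p = 0.980) among probes not brighter in liver or kidney. In liver and kidney slide stays open, because 1 genotype has a single library on slide 2, where the clock medians were 0.16 (adjusted p = 0.135) and 0.28 (0.0044). Whether the Glo1 genotype itself shifts these genes stays open, as 0 libraries have a collection time in their label.

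Tests of sex were chosen after the Xist probes were seen at the floor in libraries labelled female. Of the 14 male-biased liver genes fixed for the list, 78.6% lay in liver over 1 log2 unit above the same probe's lowest mean in the other tissues. Slco1a1, Ugt2b38 and Moxd1 did not. The comparison is between tissues and has no reference level of female liver. Genes that liver expresses in both sexes would pass it too, so this share does not decide the sex. Failure of the Xist probes could leave Xist dark in females too, but only 15% of 13 female-biased genes passed the same limit in liver, Acot3 and Cyp17a1, which argues against it. Epididymal genes, such as Lcn8 at 14.83 in Glo1+/- adipose 3, occur in gonadal fat.

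Splits of the probe counts within a tissue were chosen after the counts were seen, and splits of the list counts were planned. The 6 libraries of a tissue allow 10 splits, too few for a share under 0.05. In liver the real split called 169 probes and the highest other 0, so 1 split of 10 reached the count, and in kidney the real split called 98, the highest other 9, and again 1 reached it. In aorta the real split called 0 and the highest other 1, so all 10 reached it. In adipose tissue 2 splits reached the real count of 1, and WT 1 and 2 with Glo1+/- 1 against the rest called 64, which points to a structure of the samples other than genotype, beside the liver and kidney transcripts of these libraries. Among the 4 adipose splits that part all 3 pairs, the others called 0 probes, and 13, 5 and 8 lists where the real split called 11. For lists the real and the highest other count were 11 and 17 in adipose tissue, 8 and 12 in liver, 9 and 13 in kidney, and 17 and 19 in aorta. The real list count was reached by 6 splits in adipose tissue and by 4 in each of liver, kidney and aorta.

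Splits of all 24 libraries within their tissues were planned for the average and the difference, and the placing of called genes was tested after they were seen. The real average count of 69, which includes Ide, Bcl6, Slc27a1 and Gstt2, was reached by 1 of 100 splits, the real one, with 58 as the highest other. This argues against chance only if libraries of different tissues are independent. The splits regroup each tissue on its own, while same-numbered WT libraries share clock deviations across tissues (mean r 0.597), and with values averaged over the tissues 0 of the 69 probes passed. The difference count of 72 was reached by 11 of 100, with 195 as the highest other, so this count, which includes Gpcpd1, is not beyond what other groupings of these libraries give.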

How the results depend on the processing

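Adipose tissue had 1 called probe, Tuba1a, and 11 called lists. The probe count was 164 in a single fit of all 24 arrays, 0 among probes above the median, 59 with robust eBayes, 19 with array weights, 0 without both libraries numbered 1, 15 among probes not brighter in liver or kidney, and 0 to 176 with 1 library left out. Tuba1a was not among the 164 (adjusted p = 0.137), and without a trend it did not pass (0.063) and 1 other probe did. The list count was 0 with an estimated correlation, 0 with fry, 6 among probes not brighter in liver or kidney and 8 to 14 with 1 library left out. Among those probes 3 lists turned direction: bile acid and lipoprotein metabolism at 0.33, clock at 0.15, below the other genes by camera, and acute phase at -0.035, above them.

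With the replicate number as a block, 49 probes of adipose tissue passed (13 higher, 36 lower) and 12 lists, the added list being kidney tubule. The blocked count was 289 in liver, 74 in kidney and 0 in aorta, 80 for the average effect (44 of the 69 shared) and 65 for the difference. In kidney the block ended the gluconeogenesis call (adjusted p = 0.056). The same-numbered libraries correlated across probes, which are not independent replicates, at 0.667, 0.170 and 0.336 in adipose tissue, where number 2 correlated better with another number (0.293). In liver the values were 0.074, 0.051 and 0.230, in kidney 0.065, 0.014 and -0.0075, and in aorta 0.107, -0.110 and -0.037. Liver 3, kidney 1 and aorta 1 correlated best with their own number, and the other numbers of these tissues did not. In none of these tissues were all values above the limit of 0.1, so they were not treated as paired. A random block of genotype and number over the tissues had a correlation of -0.0076 and gave 72 probes for the average.

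Liver had 169 called probes and 8 lists. The probe count was 4 without a trend, 340 with array weights, 168 in a single fit of all arrays, 402 with slide added to that fit, 1379 within slide 2, and 22 to 695 with 1 library left out. With the mean of a gene's probes 41 genes passed, where the called probes name 63 higher and 77 lower genes. The Glo1 change was -0.88 and did not pass in a single fit of all arrays (adjusted p = 0.171) or without a trend (0.066), nor at -0.76 with slide in that fit (0.480). Lists numbered 0 with an estimated correlation and 0 with fry, and 7 to 12 with 1 library left out.

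Kidney had 98 called probes and 9 lists. The probe count was 20 in a single fit of all arrays, 17 without a trend, 153 with robust eBayes, 20 within slide 2, 16 with slide added to the fit of all arrays, and 19 to 108 with 1 library left out. With the mean of a gene's probes 27 genes passed, where the called probes name 48 higher and 36 lower genes. The Glo1 change was -0.88 and did not pass in a single fit of all arrays (adjusted p = 0.451), without a trend (0.150), with robust eBayes (0.107) or with the mean of a gene's probes (0.084). It did not pass within slide 2 (-0.96, adjusted p = 0.206) or with slide in the fit of all arrays (-0.96, 0.881), and lay between -1.09 and -0.71 with 1 library left out. Lists numbered 0 with an estimated correlation, 3 with fry, and 7 to 10 with 1 library left out.

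Aorta had 0 called probes and 17 lists. The probe count was 18 in a single fit of all arrays, 349 without both libraries labelled 3, and 0 with any 1 library left out. Without both labelled 3, whose Glo1 values overlap with the other genotype, Glo1 fell by 1.28 (adjusted p = 0.0016), a fall that this choice enlarged. With 1 library left out the Glo1 change lay between -0.98 and -0.33. Lists numbered 0 with an estimated correlation, 0 with fry and 16 to 18 with 1 library left out. Without the library labelled Glo1+/- aorta 3 the medians that turned were brown and beige adipocyte 0.093, oxidative phosphorylation 0.042, glycolysis 0.044, acute phase -0.016 and hepatocyte -0.18. Without both labelled 3 they were brown and beige adipocyte 0.039, oxidative phosphorylation 0.017, acute phase -0.017 and hepatocyte -0.28. Glycolysis kept its sign there at -0.025 and lay above the other genes by camera. The cell cycle turned to 0.091 without WT 3. With 1 library left out the medians ran from -1.36 to 0.093 for brown and beige adipocyte, -0.44 to 0.042 for oxidative phosphorylation, -0.39 to 0.044 for glycolysis, -0.30 to 0.091 for the cell cycle, -0.016 to 0.52 for acute phase and -0.18 to 0.58 for hepatocyte genes.

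The average effect had 69 called probes. The count was 117 among probes above the median, 113 without a trend, 6 without liver, 19 without kidney, 374 without aorta, 0 for values averaged over the tissues, 405 without the library labelled Glo1+/- aorta 3, and 6 to 284 with 1 number of a genotype left out. With slide as a block it was 85, of which 24 were shared. The difference had 72, and 138 with slide as a block, 133 without a trend, 12 without adipose tissue, 0 without liver, 9 without kidney, 220 without aorta, 320 without the library labelled Glo1+/- aorta 3, and 9 to 290 with 1 number left out. A spread per tissue gave 63 and 99. The correlations across genes with aorta moved to 0.118 for adipose tissue, 0.162 for liver and 0.098 for kidney without that library.

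Of the named genes called in liver, 1 of 41, Gpcpd1, was kept in every alternative, and 0 of 31 in kidney, 0 of 1 in adipose tissue, and 0 of 12 for each of the average and the difference. Weaker were 289 of 738 values in liver, 218 of 558 in kidney, 7 of 18 in adipose tissue, 39 of 228 for the average and 32 of 216 for the difference, and 0 turned direction. Named genes not called became stronger in 110 of 1255 values in adipose tissue, 36 of 1680 in aorta, 25 of 717 in kidney and 32 of 411 in liver. Of the list values 33 of 151 in adipose tissue, 57 of 221 in aorta, 32 of 117 in kidney and 29 of 104 in liver were weaker. Values have a floor near 8 and their background correction is not given in the sources used here, so changes of dim probes can be understated. The cause of these moves was not tested.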

Other observations

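Both tests of neighbouring genes were chosen after the average effects were seen. The dicarbonyl detoxification list had average effects with a median of 0.015 over 17 genes, and Glo1 was its only called member. In kidney its median was 0.099 (camera adjusted p = 0.199), so neither a response of this pathway nor its absence was shown. In liver and kidney the oxidation genes Cyp4a31, Eci2 and Slc25a20 rose together, and in liver the synthesis genes Acly, Elovl6, Me1 and Acaca fell, a direction known from fasted liver. No list of fasting genes was fixed. Of genes known from fasted liver Fgf21 (0.58, adjusted p = 0.019) and Lpin1 (1.14, 0.019) were called up, and Pdk4 (-0.55, 0.190), Pck1 (0.29, 0.261) and G6pc (-0.13, 0.895) were not called. The synthesis list had -0.13 (adjusted p = 0.568) within slide 2. The same libraries had lower Egr1 and Bcl6. Feeding state or time of collection may contribute to this set. Same-numbered WT libraries of different tissues share their clock deviations (mean r 0.597, exact permutation p = 0.0046). For Glo1+/- libraries this was not shown (mean r -0.020, exact permutation p = 0.542). Without aorta, where 1 Glo1+/- library carries a white fat profile, they had 0.210 (exact permutation p = 0.083 of 36), so a contrast between the genotypes was not shown either. Whether a number names 1 animal is not known, and these correlations do not show that the genotypes were collected differently, so the cause stays open.

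A candidate for work with animals collected together is Ide, which degrades insulin and had effects of -0.54, -0.55, -0.67 and -0.59 in the 4 tissues. Slc27a1 and Gstt2, higher in each tissue, are others. Genes chosen here were chosen after their values were seen. A segment of other strain origin around the targeted gene could move neighbours of Glo1 in every tissue. The 50 nearest measured genes had a median absolute average effect of 0.052, at percentile 30.7 of 7997 windows of that size, and 0 neighbours had an adjusted p under 0.05, with 7 under 0.05 unadjusted by limma. The percentile was 21.8 without the library labelled Glo1+/- aorta 3, and then 1 neighbour passed, Fkbp5 (adjusted p = 0.036). This argues against a segment in which many genes changed, and leaves single genes open. Segments elsewhere that went with the genotype might place called genes near each other. Among 57 called genes 12 pairs lay within 25 gene positions, such as Ide with Cyp2c55, Nqo2 with Eci2 and Egr1 with Eif4ebp3, where random sets gave 8.54 on average (one-sided permutation p = 0.150), so the question stays open.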
